A study of Mus musculus with 11 samples.

How the data were processed

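Poly(A) RNA sequencing libraries of 11 mouse AKP organoid samples were analysed. Per the submitters' processing notes, reads were aligned with Bowtie to mm9 and quantified with RSEM; the versions and the gene annotation are not given in the sources used here. Per the labels, RNA was isolated with an Ambion PureLink kit and libraries were made with NEBNext Ultra II Directional reagents. The deposited table holds RSEM expected counts for 23224 gene names, 25 of which are dates where a spreadsheet replaced a symbol; these were kept under the deposited name. Expected counts were rounded to whole numbers. Library totals ranged from 14109182 to 22154456.

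Samples were grouped by their labels as naive (3), C57Bl6 tumour-derived (3), RAG2KO tumour-derived (3), constitutive SOX17OE (1) and inducible SOX17OE (1). The titles of the tumour libraries each carry a different number, which may be that of an animal. Nothing in the sources used here states that the naive replicates came from separate cultures or the tumour replicates from separate mice. The p-values therefore measure only the spread between these samples. The comparisons were each tumour group against naive, the tumour groups against each other, the mean of the 2 SOX17OE lines against naive, each line alone against naive, and the overlap of the changes against naive. The groups, comparisons, gene lists, named-gene rule and the alternatives, except those said below to be added later, were fixed before the data were examined.

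Genes were filtered with filterByExpr, which left 13720, scaled by TMM and fitted with the robust quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with all 11 libraries in 5 groups. The common dispersion was 0.0641, a biological coefficient of variation of 25.3%, with 6 residual and a median of 4.16 prior degrees of freedom. A single SOX17OE library was thereby assumed to vary like the other groups. Tests were two-sided, a gene was called at a Benjamini-Hochberg adjusted p under 0.05, and a standard error is the absolute log2 fold change divided by the square root of F. Where a group was at 0 counts in each library, the lower bound of its fold used a floor of 3 counts per library, and with 1 to 3 counts the ratio is given with a 95% counting interval. Shares of counts have 95% Wilson intervals.

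32 gene lists written from general knowledge held 688 members, of which 680 matched a row, 10 of them under an older symbol. 30 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and adjusted over the lists of a comparison; the Paneth cell list and the list of T, B and NK cell markers had fewer. Counts adjusted over the list alone use only the genes of that list. The lists were those of intestinal stem cells, Wnt/beta-catenin targets, fetal intestine and repair, YAP/TAZ targets, endoderm and SOXF factors, MHC class I, MHC class II, interferon gamma signalling, interferon gamma induced and type I interferon induced genes, chemokines, NF-kappaB targets, checkpoint ligands, absorptive, goblet, enteroendocrine, tuft, gastric and identity genes, proliferation, junctions, epithelial-mesenchymal transition, glycolysis and hypoxia, cholesterol synthesis, unfolded protein response, immediate early genes, p53 targets, and fibroblast, endothelial and myeloid markers.

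The text names Sox17, Ifngr1, Ifngr2, Irf1, B2m, H2-K1, H2-D1, Tap1, Cd274, Cxcl10, Lgr5, Ascl2, Ly6a, Anxa1, Trp53, Apc and Rag2 in each comparison. It adds the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries, without unnamed predicted genes and ribosomal pseudogenes. From each list the rule takes the first 4 called members by adjusted p, and the text gives the first 2 of each passing list, a limit set after the results were seen. A few genes that the rule gives are left out of the text, and counts of genes given by the rule include them. Other names, among them Rn45s, host cell markers and further list members, were chosen after their values were seen.

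Alternatives were the size factors of DESeq2, upper quartile scaling, library totals, no filter, a filter of 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma voom with sample weights, a non-robust fit, each of the 11 libraries left out, a fit of only the groups compared, a block for the replicate number, a fit of naive and SOX17OE libraries with the lines as 2 samples of 1 group, camera with an estimated correlation, and fry. A Rn45s covariate and a fit without chromosome 13 genes were added after seeing the data. Fold bounds and counting ratios with a library left out were also added then, with the scaling of all libraries kept, and those that moved more than 1.5 times are given. The chromosome of a gene and the order of neighbouring genes were taken from the GRCm38 gene table by gene name, and no coordinates are given. On simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, the test recovered 52% and 74% for C57Bl6 against naive, 45% and 74% for RAG2KO against naive, 47% and 73% between recipients, 42% and 85% for the mean of the lines, 11% and 60% for the constitutive and 7% and 53% for the inducible line. Unchanged genes made up 8 of 134, 10 of 129, 8 of 128, 10 of 137, 2 of 73 and 7 of 67 calls. A simulated shift of the YAP/TAZ list passed with 0 of the 29 other lists. The simulated genes were drawn independently, whereas the estimated correlation of this list was 0.35 for C57Bl6 against naive. The simulation therefore cannot show how the list test acts on correlated genes.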

Results

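Gene expression was measured by poly(A) RNA sequencing in 11 libraries of mouse AKP colon cancer organoids, which carry alterations of cancer genes, Apc and Trp53 among them. 3 libraries came from naive organoids. 3 came from organoids re-grown from primary tumours in immunocompetent C57Bl6 mice, and 3 from organoids re-grown from tumours in immunodeficient RAG2KO mice, which lack an enzyme that T and B cells need to mature. The tumours grew after naive organoids had been placed in the colon by colonoscopy, and per the submitters' design text the re-derived cultures were kept until cancer cells alone were left. 2 further libraries came from naive organoids that carried a SOX17 overexpression construct (SOX17OE), 1 constitutive and 1 doxycycline-inducible; each line has no replicate. Whether doxycycline was given is not stated in the sources used here.

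Library totals were 14109182, 22154456 and 20213591 expected counts in the naive, 19024262, 17541721 and 18658006 in the C57Bl6 and 15412611, 17656757 and 16836583 in the RAG2KO libraries. The constitutive line had 17521173 and the inducible line 17364887. Values are counts scaled by TMM library size (CPM), given as mean ± SD with n = 3 unless a line is named. Of 23224 listed genes, 13720 had enough counts to be tested. Rn45s, the ribosomal RNA precursor, took 2.42 to 4.99% of counts in the naive, 2.21 to 3.77% in the C57Bl6 and 6.56 to 8.54% in the RAG2KO libraries. It took 6.39% in the constitutive line (95% Wilson interval 6.38 to 6.41%) and 3.71% in the inducible line (3.70 to 3.72%). The widest of the 11 Wilson intervals was ± 0.013 percentage points, and intervals and floors throughout cover counting error only. The first principal component of the tested genes held 36.4% of the variance and the second 24.8%.

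**Figure D1:**
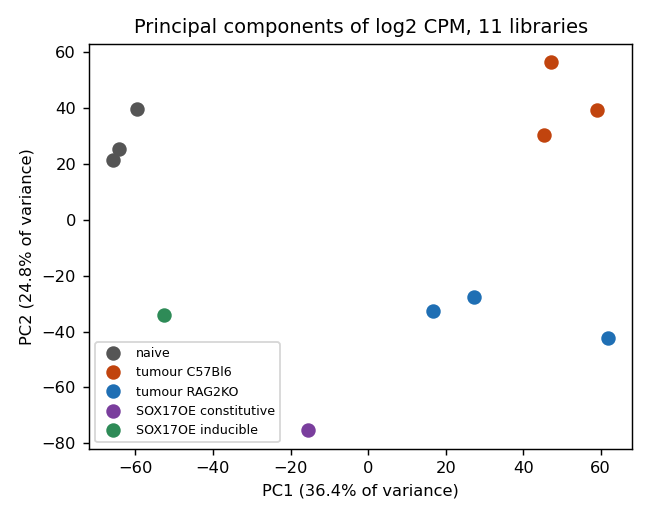
Each point is 1 of the 11 libraries, coloured by group, on the first (36.4% of variance) and second (24.8%) principal components of log2 CPM of the tested genes. The naive, C57Bl6 and RAG2KO libraries form 3 separate clusters.

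The comparison of C57Bl6 tumour-derived with naive organoids asks which genes differ after growth as a tumour in an immunocompetent mouse. Sox17, a SOXF transcription factor of the endoderm, averaged 35.0 ± 34.2 CPM against 0.102 ± 0.0974 CPM in naive organoids and rose by 8.54 on the log2 scale (SE 0.99, adjusted p = 7.63e-04). Its 3 tumour-derived libraries held 18.4, 12.4 and 74.3 CPM. Irf1, an interferon-responsive transcription factor, rose from 31.9 ± 1.93 to 57.2 ± 12.9 CPM (log2 fold change 0.84, SE 0.16, adjusted p = 0.00674). B2m, the light chain of MHC class I, rose from 33.4 ± 0.996 to 73.2 ± 6.29 CPM (log2 fold change 1.13, SE 0.15, adjusted p = 0.00118).

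The interferon gamma receptor gene Ifngr1 had 70.5 ± 11.5 CPM against 63.9 ± 7.09 CPM (log2 fold change 0.14, SE 0.15, adjusted p = 0.564). Lgr5, a marker of intestinal stem cells, had 54.0 ± 9.64 against 57.6 ± 12.2 CPM (log2 fold change -0.09, SE 0.32, adjusted p = 0.880). The other fixed genes did not pass the test either, with log2 fold changes of 0.0038 for Ifngr2, 0.16 for H2-K1, 0.33 for H2-D1, -0.03 for Tap1 and 0.62 for Cd274. They were -1.03 for Cxcl10, -0.76 for Ascl2, 0.18 for Ly6a, 0.45 for Anxa1, -0.04 for Trp53 and -0.03 for Apc (adjusted p from 0.0916 to 0.994). Rag2 had 0 to 2 counts in each library and was not tested.

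The largest rises included genes that naive organoids did not express at this depth. Igfbp4, a binding protein of insulin-like growth factors, reached 203 ± 66.9 CPM against 1 count in the 3 naive libraries (ratio 11605, 95% counting interval 2083 to 458427, adjusted p = 4.19e-06). Without naive replicate 1, which held the count, it was at least 1476-fold above the floor of 3 counts per library, and without naive replicate 2 or 3 the ratio was 7023 or 7393. Mmp14, a membrane-bound matrix metalloprotease, reached 30.4 ± 28.0 CPM against 1 count (ratio 1809, interval 324 to 71487, adjusted p = 4.87e-04). Its ratio was 850 without C57Bl6 replicate 3 and 1095 without naive replicate 2, and it was at least 176-fold higher without naive replicate 3, which held the count. 4 more genes had 0 counts in each naive library, and against the floor Scara3 was at least 143-fold, the collagen chaperone Serpinh1 at least 108-fold, Fam149a at least 77.3-fold and Dzip1l at least 55.8-fold higher. Without C57Bl6 replicate 1 these were at least 92.0-fold for Scara3, 65.8-fold for Serpinh1 and 27.2-fold for Fam149a. Serpinh1 missed the threshold without naive replicate 2 (adjusted p = 0.0535) or naive replicate 3 (0.0533). The largest falls were those of Gvin1 (-5.68, SE 0.61, adjusted p = 4.06e-04), Ms4a8a (-5.67, SE 0.24, adjusted p = 3.61e-06), Cyp2c55 (-5.65, SE 0.84, adjusted p = 0.002), the phosphodiesterase Pde4b (-5.48, SE 0.61, adjusted p = 5.01e-04), Lrrc19 (-5.28, SE 0.46, adjusted p = 1.07e-04) and the mast cell chymase Cma1 (-5.19, SE 0.59, adjusted p = 6.96e-04). Gvin1 and Cyp2c55 belong to gene families with similar sequences, so reads may have been divided between members.

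Of 15 genes of the gastric and foregut epithelium tested 10 rose, 0 fell and 5 did not pass (11 and 0 adjusted over the list alone), and the list passed (adjusted p = 1.41e-09, and adjusted p = 0.0626 with an estimated correlation). The water channel Aqp5 rose from 0.1246 ± 0.147 to 154 ± 57.7 CPM (log2 fold change 10.06, SE 0.72) and Onecut2 from 0.905 ± 0.0639 to 96.1 ± 54.1 CPM (6.73, SE 0.55). Among the 6 tuft cell genes tested 4 rose, 1 fell and 1 did not pass (4 and 1 over the list alone; adjusted p = 1.41e-09, and 0.0169 with an estimated correlation). The tuft cell genes that rose most clearly were the villin relative Avil (4.74, SE 0.32) and the prostaglandin synthase Ptgs1 (5.76, SE 0.40). Pou2f3 and Trpm5, also on the list, had too few counts to test. Absorptive colonocyte genes fell in 9 of 17 members and rose in 0 (9 and 0 over the list alone; adjusted p = 1.69e-07, and 0.0921 with an estimated correlation). The transmembrane mucin Muc13 fell from 296 ± 38.9 to 10.5 ± 4.98 CPM (log2 fold change -4.81, SE 0.40), and Lypd8, listed as 2210415F13Rik, from 17.1 ± 2.34 to 1.86 ± 1.75 CPM (-3.20, SE 0.50).

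The YAP/TAZ target list rose in 13 of 20 members and fell in 0 (17 and 0 adjusted over the list alone; adjusted p = 1.3e-08, and adjusted p = 0.328 with an estimated correlation). Its clearest members were the LIM protein gene Ajuba, listed as Jub (1.30, SE 0.12), and Gadd45b (1.01, SE 0.14). MHC class I presentation genes rose in 7 of 22 members and fell in 0 (10 and 0 over the list alone; adjusted p = 6.21e-05, and 0.222 with an estimated correlation), with the peptide-loading factor Tapbp at 1.84 (SE 0.20) and the proteasome activator Psme1 at 1.02 (SE 0.12). Unfolded protein response genes fell in 4 of 20 members and rose in 0 (8 and 0 over the list alone; adjusted p = 8.27e-04, and 0.724 with an estimated correlation). The stress-response factor Atf4 fell by 0.70 (SE 0.11) and the asparagine synthetase gene Asns by 0.71 (SE 0.17). Asns missed the threshold without naive replicate 1 (adjusted p = 0.0642), naive replicate 3 (0.0515), C57Bl6 replicate 2 (0.0624) or C57Bl6 replicate 3 (0.0699).

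Wnt/beta-catenin targets rose in 8 of 21 members and fell in 1 (9 and 2 adjusted over the list alone; adjusted p = 0.027, and adjusted p = 0.724 with an estimated correlation; 0.272 without C57Bl6 replicate 3). The members that rose included Dkk2 (3.76, SE 0.31), which encodes a secreted antagonist of Wnt signalling, and the cyclin Ccnd1 (0.89, SE 0.15). Epithelial-mesenchymal transition genes rose in 5 of 19 members and fell in 0 (7 and 0 over the list alone; adjusted p = 0.0321, and 0.760 with an estimated correlation; 0.0533 without C57Bl6 replicate 1), led by Mmp14 and the fibronectin gene Fn1 (5.42, SE 0.76). Fibroblast and smooth muscle markers rose in 2 of 6 members and fell in 0, with a median of 1.13 (adjusted p = 0.147, and 0.0478 with fry). Intestine and colon identity factors fell in 5 of 15 members and rose in 3 (5 and 3 over the list alone; adjusted p = 0.0493, and 0.724 with an estimated correlation). The homeobox gene Cdx1 fell by 4.54 (SE 0.59) and Hoxb9 by 1.11 (SE 0.13), while Hoxa11 (1.71) rose. This list missed the threshold without naive replicate 3 (adjusted p = 0.232), C57Bl6 replicate 1 (0.148) or the constitutive line (0.0509).

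Fetal intestine and repair genes rose in 7 of 24 members and fell in 4 (11 and 6 adjusted over the list alone; adjusted p = 0.036, and adjusted p = 0.760 with an estimated correlation), with the secreted chaperone clusterin, Clu, at 5.47 (SE 0.51) and Msln at 2.36 (SE 0.30). This call ended without naive replicate 1 (0.0896), naive replicate 2 (0.122), C57Bl6 replicate 1 (0.0780) or C57Bl6 replicate 2 (0.0659). Immune checkpoint and regulatory ligands rose in 6 of 19 members and fell in 2 (6 and 2 over the list alone; adjusted p = 0.027, and 0.724 with an estimated correlation; 0.0939 without C57Bl6 replicate 1), with the galectin Lgals9 at 3.30 (SE 0.25) and the B7 family ligand Vtcn1 at 4.03 (SE 0.33). NF-kappaB targets rose in 3 of 19 members and fell in 0 (5 and 0 over the list alone; adjusted p = 0.0321, and 0.760 with an estimated correlation), and the call ended without naive replicate 1 (0.0568) or C57Bl6 replicate 1 (0.0780). The adhesion molecule Icam1 rose by 0.89 (SE 0.19; adjusted p = 0.0555 without naive replicate 1) and Ier3 by 1.25 (SE 0.33). The call of Ier3 ended without naive replicate 1 (0.0897), 2 (0.124) or 3 (0.0779) or without C57Bl6 replicate 1 (0.0834) or 3 (0.0625).

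Interferon gamma induced genes rose in 5 of 21 members and fell in 0 (6 and 0 adjusted over the list alone; adjusted p = 0.0454, and adjusted p = 0.724 with an estimated correlation), with Parp14 at 1.56 (SE 0.27) and the guanylate-binding protein Gbp3 at 3.48 (SE 0.65). Gbp3 belongs to a family whose reads may have been divided between members. The call of this list ended without naive replicate 3 (0.0505), C57Bl6 replicate 1 (0.0780), C57Bl6 replicate 2 (0.0710) or the constitutive line (0.0509). Type I interferon induced genes rose in 2 of 26 members and fell in 1 (adjusted p = 0.742). Proliferation genes rose in 0 of 30 members and fell in 0 (adjusted p = 0.706), and chemokines and cytokines rose in 7 of 23 and fell in 1 (adjusted p = 0.0629). The chemokine list passed without RAG2KO replicate 2 (0.0196) or RAG2KO replicate 3 (0.0139), and the immediate early list (2 higher, 0 lower of 21, adjusted p = 0.607) without naive replicate 3 (0.0250).

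Over all genes, 2106 of 13720 changed between C57Bl6 tumour-derived and naive organoids, 1304 higher and 802 lower, and voom called 4067. The count was 1096 without naive replicate 1 and 1030 without naive replicate 2. With the log2 share of Rn45s as a covariate, a choice made after seeing the data, each of the 40 called genes that the naming rule gave the text passed. Those 40 follow the limit per list, which was set after the results were seen. Among all genes that the rule names in this comparison, 91 kept their side of the threshold with the covariate and 10 no longer passed. The adjusted fold changes of the 2106 genes had a slope of 0.988 on the unadjusted ones (0.976 to 1.004 with a library left out), and the median SE went from 0.273 to 0.282. 13 of the 30 lists passed, 7 lists without C57Bl6 replicate 1, and the tuft cell list passed with an estimated correlation. In C57Bl6 replicate 2 the genes of chromosome 13 had a median log2 difference from naive of -0.77, and none of the genes named in this comparison lies on chromosome 13 in the GRCm38 annotation. The median, mean and tested direction of a list differed in sign for stem cell markers (0.05, -0.30, up), enteroendocrine genes (1.90, -0.17, down), epithelial junction genes (0.07, -0.21, down), p53 targets (-0.10, 0.11, down), proliferation genes (8.2e-04, -0.0018, down) and myeloid markers (0.16, -0.34, down).

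The comparison of RAG2KO tumour-derived with naive organoids asks the same question for growth in an immunodeficient mouse. Sox17 averaged 20.6 ± 4.71 CPM against 0.102 ± 0.0974 CPM and rose by 7.77 on the log2 scale (SE 0.99, adjusted p = 0.00104). The interferon-pathway genes Irf1 (1.63, SE 0.16, adjusted p = 2.32e-04) and B2m (1.37, SE 0.15, adjusted p = 4.38e-04) rose as well. Lgr5 fell from 57.6 ± 12.2 to 16.9 ± 7.62 CPM (log2 fold change -1.77, SE 0.33, adjusted p = 0.00478). Anxa1 rose by 0.72 (SE 0.18, adjusted p = 0.0152), and its call ended without naive replicate 2 (0.0665) or RAG2KO replicate 2 (0.0519).

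The second receptor chain gene Ifngr2 rose by 0.66 (SE 0.19, adjusted p = 0.025) and the chemokine gene Cxcl10 fell by 1.77 (SE 0.51, adjusted p = 0.0278). Ifngr2 missed the threshold without naive replicate 1 (0.0732), naive replicate 2 (0.0910) or RAG2KO replicate 2 (0.0842), and Cxcl10 without naive replicate 2 (0.0616), naive replicate 3 (0.0907), RAG2KO replicate 1 (0.0792) or RAG2KO replicate 3 (0.0645). Apc fell by 0.53 (SE 0.18, adjusted p = 0.0485). The call of Apc ended without naive replicate 1 (0.0936), 2 (0.103) or 3 (0.114), without C57Bl6 replicate 3 (0.0664) and without RAG2KO replicate 1 (0.111), 2 (0.106) or 3 (0.0844). Ifngr1 had 60.2 ± 4.21 against 63.9 ± 7.09 CPM (log2 fold change -0.09, SE 0.15, adjusted p = 0.691). The log2 fold changes of the other fixed genes that did not pass were 0.24 for H2-K1, 0.32 for H2-D1, 0.91 for Tap1, 1.34 for Cd274, -0.46 for Ascl2, 0.52 for Ly6a and 0.46 for Trp53 (adjusted p from 0.0682 to 0.398).

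Several of the largest rises rested on RAG2KO replicate 2. Igfbp4 reached 24.8 ± 7.64 CPM against 1 count in the naive libraries (ratio 1448, 95% counting interval 259 to 57255, adjusted p = 3.45e-05; at least 180-fold without naive replicate 1, which held the count, and ratios of 876 and 923 without naive replicates 2 and 3), and Tmem150c was at least 32.5-fold higher than the floor of 3 counts per library (adjusted p = 3.32e-04). The protease inhibitor gene Serpine2 had 0.270, 50.7 and 0.312 CPM in the 3 RAG2KO libraries against 1 naive count (ratio 1057, interval 189 to 41800, adjusted p = 0.0233). Without RAG2KO replicate 2 its log2 fold change moved from 9.44 to 3.59 (adjusted p = 0.0850) and its ratio to 16.8 (interval 2.33 to 738). Its call also ended without naive replicate 1 (0.0787, at least 125-fold), 2 (0.0893, ratio 640) or 3 (0.0892, ratio 673). The bone sialoprotein gene Ibsp was at least 35.0-fold and the collagen gene Col8a1 at least 40.2-fold higher than the floor, and both calls ended without RAG2KO replicate 2 (Ibsp 0.0616 and at least 3.91-fold, Col8a1 0.0735 and at least 10.2-fold). They ended too without naive replicate 1 (0.0664 and 0.0623), 2 (0.0853 and 0.0812) or 3 (0.0843 and 0.0821). Serpinh1 was at least 44.3-fold higher (14.2-fold without RAG2KO replicate 2), and missed the threshold without naive replicate 2 (0.0549) or 3 (0.0568).

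The largest falls included those of the uroplakin Upk1b (-4.37, SE 0.93, adjusted p = 0.00821), the EGF receptor ligand Ereg (-3.77, SE 0.75, adjusted p = 0.00701), Mrc1 (-3.75, SE 0.86, adjusted p = 0.0113), the kinase Prkaa2 (-3.66, SE 0.35, adjusted p = 1.89e-04) and Cma1 (-3.56, SE 0.54, adjusted p = 0.00211). Mrc1 was at -5.65 without RAG2KO replicate 2.

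Type I interferon induced genes rose in 15 of 26 members and fell in 0 (18 and 0 adjusted over the list alone; adjusted p = 8.84e-07, and adjusted p = 0.637 with an estimated correlation). The deubiquitinase Usp18 rose from 0.733 ± 0.0842 to 45.5 ± 19.2 CPM (log2 fold change 5.93, SE 0.75) and the antiviral synthetase Oas1a from 2.44 ± 0.268 to 20.3 ± 8.78 CPM (3.05, SE 0.36). Oas1a has close paralogs whose reads may have been divided between them. MHC class I presentation genes rose in 13 of 22 members and fell in 0 (14 and 0 over the list alone; adjusted p = 1.24e-05, and 0.196 with an estimated correlation), with Psme1 at 1.57 (SE 0.12) and Tapbp at 1.96 (SE 0.20). Interferon gamma induced genes rose in 8 of 21 members and fell in 2 (9 and 2 over the list alone; adjusted p = 0.032, and 0.637 with an estimated correlation), with Parp14 at 2.34 (SE 0.27) and the GTPase Irgm2 at 3.95 (SE 0.65), also 1 of a gene family. This call ended without C57Bl6 replicate 1 (0.0515), C57Bl6 replicate 2 (0.0575) or RAG2KO replicate 2 (0.0849). The share of Rn45s was 6.56 to 8.54% in the RAG2KO and 2.42 to 4.99% in the naive libraries.

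Proliferation genes fell in 15 of 30 members and rose in 0 (19 and 0 adjusted over the list alone; adjusted p = 1.9e-07, and adjusted p = 0.637 with an estimated correlation). Mki67, a marker of cycling cells, fell from 549 ± 16.8 to 235 ± 57.3 CPM (log2 fold change -1.22, SE 0.18) and the spindle checkpoint kinase Bub1b by 0.89 (SE 0.14). Unfolded protein response genes fell in 12 of 20 members and rose in 0 (14 and 0 over the list alone; adjusted p = 3.84e-08, and 0.542 with an estimated correlation), with Trib3 at -1.95 (SE 0.22) and Asns at -1.24 (SE 0.17). Tuft cell genes rose in 3 of 6 members and fell in 0 (4 and 0 over the list alone; adjusted p = 7.14e-09, and 0.019 with an estimated correlation), with Cd24a at 3.77 (SE 0.24) and Avil at 4.80 (SE 0.32). Gastric and foregut genes rose in 7 of 15 members and fell in 0 (8 and 0 over the list alone; adjusted p = 1.21e-05, and 0.196 with an estimated correlation), with Onecut2 at 5.46 (SE 0.54) and Aqp5 at 6.18 (SE 0.74).

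Wnt/beta-catenin targets rose in 7 of 21 members and fell in 2 (8 and 2 adjusted over the list alone; adjusted p = 0.00823, and adjusted p = 0.613 with an estimated correlation). Those that rose included Dkk2 (4.89, SE 0.32) and Notum (3.86, SE 0.46), and Lgr5 and Myc fell. Fetal intestine and repair genes rose in 10 of 24 members and fell in 3 (11 and 3 over the list alone; adjusted p = 0.0102, and 0.729 with an estimated correlation; 0.0849 without RAG2KO replicate 2), with Msln at 2.45 (SE 0.31) and Clu at 3.68 (SE 0.47). Chemokines and cytokines rose in 10 of 23 members and fell in 1 (12 and 1 over the list alone; adjusted p = 0.0178, and 0.673 with an estimated correlation), with the neutrophil chemokine Cxcl3 at 4.76 (SE 0.68) and Tnf at 2.33 (SE 0.33). Immune checkpoint and regulatory ligands rose in 6 of 19 members and fell in 2 (7 and 2 over the list alone; adjusted p = 0.0368, and 0.637 with an estimated correlation), with Lgals9 at 3.64 (SE 0.25) and Vtcn1 at 4.06 (SE 0.33). That call ended without naive replicate 1 (0.0627), C57Bl6 replicate 1 (0.0522) or RAG2KO replicate 2 (0.106).

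YAP/TAZ targets rose in 5 of 20 members and fell in 2 (adjusted p = 0.234) and absorptive colonocyte genes fell in 5 of 17 and rose in 0 (adjusted p = 0.1298). Some lists passed with a library left out. Stem cell markers (1 higher, 5 lower of 19, adjusted p = 0.0725) passed without naive replicate 1 (0.0446) or RAG2KO replicate 3 (0.0259), and NF-kappaB targets (5 higher, 0 lower of 19, adjusted p = 0.1298) without RAG2KO replicate 3 (0.0188). Epithelial-mesenchymal transition genes (5 higher, 1 lower of 19, adjusted p = 0.058) passed without naive replicate 3 (0.0471), RAG2KO replicate 1 (0.00739) or RAG2KO replicate 3 (0.00315). Fibroblast and smooth muscle markers rose in 2 of 6 members and fell in 0, with a median of 2.28 (adjusted p = 0.118, and 0.0453 with fry). Glycolysis and hypoxia genes (2 higher, 6 lower of 26, adjusted p = 0.0725) passed without naive replicate 1 (0.0221), naive replicate 2 (0.0377) or RAG2KO replicate 3 (0.0193). Immediate early genes (2 higher, 3 lower of 21, adjusted p = 0.0725) passed without naive replicate 1 (0.00401), naive replicate 2 (0.0309) or RAG2KO replicate 2 (0.0358).

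Over all genes, 4010 changed between RAG2KO tumour-derived and naive organoids, 2192 higher and 1818 lower, and scaling by library totals gave 1910 higher and 2323 lower. The count was 2041 without naive replicate 2 and 2466 without RAG2KO replicate 2. With the log2 share of Rn45s as a covariate, a choice made after seeing the data, 148 genes were called, and 14 of the 43 called genes that the naming rule gave the text passed. The adjusted fold changes of the 4010 genes had a slope of 1.03 on the unadjusted ones (0.914 to 1.14 with a library left out), while the median SE went from 0.2001 to 0.3687. 11 of the 30 lists passed, and the tuft cell list passed with an estimated correlation. The median, mean and tested direction differed in sign for p53 targets (0.04, 0.08, down) and myeloid markers (0.14, 0.21, down).

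**Figure D2:**
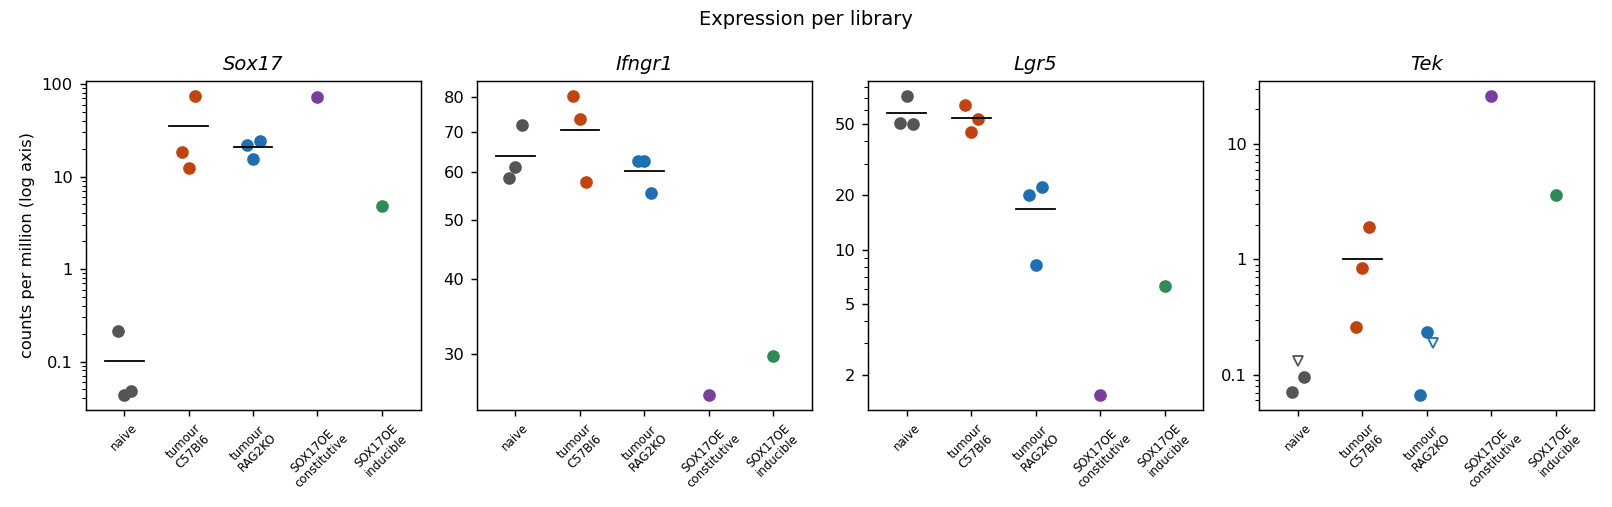
CPM on a log axis of Sox17, Ifngr1, Lgr5 and Tek in the 11 libraries by group. Filled points are libraries, black lines are group means where no library is at 0, and open triangles are libraries at 0 drawn at their floor of 3 counts. Ifngr1 was 25.7 CPM in the constitutive and 29.7 CPM in the inducible line and 55.4 to 80.3 CPM in the other libraries.

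Organoids from C57Bl6 tumours were compared with those from RAG2KO tumours to ask which genes differ with the immune status of the recipient. Usp18 had 0.943, 3.14 and 8.08 CPM in the C57Bl6 and 23.5, 58.3 and 54.7 CPM in the RAG2KO libraries, and was lower in C57Bl6 tumour-derived organoids (log2 fold change -3.48, SE 0.63, adjusted p = 0.00675). Lgr5 was higher in them, at 54.0 ± 9.64 against 16.9 ± 7.62 CPM (log2 fold change 1.68, SE 0.33, adjusted p = 0.00844). Irf1 was lower (-0.79, SE 0.16, adjusted p = 0.00855), and so was Ifngr2 (-0.66, SE 0.19, adjusted p = 0.030; 0.0865 without RAG2KO replicate 2). Sox17 had 35.0 ± 34.2 against 20.6 ± 4.71 CPM, a difference that did not pass (log2 fold change 0.77, SE 0.57, adjusted p = 0.350).

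Among the other fixed genes the log2 differences that did not pass were 0.23 for Ifngr1, -0.24 for B2m, -0.09 for H2-K1, 0.01 for H2-D1, -0.94 for Tap1 and -0.73 for Cd274. They were 0.74 for Cxcl10, -0.30 for Ascl2, -0.34 for Ly6a, -0.27 for Anxa1, -0.50 for Trp53 and 0.50 for Apc (adjusted p from 0.0673 to 0.965). The largest differences toward C57Bl6 were in Mmp14 (7.86, SE 0.91, adjusted p = 0.002), the matrix protein gene Efemp1 (ratio 302, 95% counting interval 53.9 to 11968, adjusted p = 0.00343), Bicc1 (ratio 125, interval 34.3 to 1036, adjusted p = 0.00788), the transcription factor gene Gata5 (5.99, SE 1.27, adjusted p = 0.011), Cadps (5.51, SE 1.24, adjusted p = 0.0136) and Zfp518b (4.70, SE 0.62, adjusted p = 0.00255). Gata5 was at 3.84 without C57Bl6 replicate 1, and Cadps at -0.26 (adjusted p = 0.979) with the Rn45s covariate, chosen after seeing the data. The ratio of Efemp1 was 135 without C57Bl6 replicate 1 and 194 and 201 without RAG2KO replicates 2 and 3, and it was at least 34.8-fold without RAG2KO replicate 1, which held the count. The ratio of Bicc1 was 28.4 (interval 7.43 to 241) without C57Bl6 replicate 2 and 83.1 without RAG2KO replicate 3. The largest differences toward RAG2KO were in the metallothionein Mt4 (-6.32, SE 0.56, adjusted p = 0.00111), the matrix Gla protein gene Mgp (-5.93, SE 0.49, adjusted p = 0.001), Krtap3-3 (-5.56, SE 0.78, adjusted p = 0.00301), Lmo2 (-5.53, SE 1.03, adjusted p = 0.00672), Ptn (-5.30, SE 0.82, adjusted p = 0.00395) and Ms4a8a (-4.93, SE 0.24, adjusted p = 9.1e-06). Krtap3-3 belongs to a family of similar genes.

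Type I interferon induced genes were lower in C57Bl6 tumour-derived organoids in 14 of 26 members and higher in 0 (23 and 0 adjusted over the list alone; adjusted p = 1.41e-07, and adjusted p = 0.862 with an estimated correlation). Oas1a differed by -2.11 (SE 0.34) and Rtp4 by -3.48 (SE 0.63). Proliferation genes were higher in 14 of 30 members and lower in 0 (20 and 0 over the list alone; adjusted p = 1.41e-07, and 0.862 with an estimated correlation), with the ribonucleotide reductase subunit Rrm2 at 1.15 (SE 0.20) and the mitotic kinase Plk1 at 0.999 (SE 0.18). YAP/TAZ targets were higher in 9 of 20 members and lower in 0 (10 and 1 over the list alone; adjusted p = 4.5e-05, and 0.862 with an estimated correlation), with Ptpn14 at 1.36 (SE 0.16) and Tead1 at 1.02 (SE 0.16). Absorptive colonocyte genes were lower in 3 of 17 members and higher in 0 (3 and 0 over the list alone; adjusted p = 0.00151, and 0.862 with an estimated correlation), with Muc13 at -3.83 (SE 0.39) and 2210415F13Rik at -3.86 (SE 0.51). The share of Rn45s was 2.21 to 3.77% in the C57Bl6 and 6.56 to 8.54% in the RAG2KO libraries.

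Stem cell markers were higher in 6 of 19 members and lower in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.022, and adjusted p = 0.862 with an estimated correlation), with the cell cycle kinase Cdk6 at 1.18 (SE 0.16) beside Lgr5. The call ended without C57Bl6 replicate 1 (0.0626), C57Bl6 replicate 3 (0.0531) or RAG2KO replicate 1 (0.0545). Unfolded protein response genes were higher in 6 of 20 members and lower in 0 (6 and 0 over the list alone; adjusted p = 0.0124, and 0.961 with an estimated correlation; 0.160 without C57Bl6 replicate 1), with Trib3 at 1.10 (SE 0.22) and Chac1 at 0.81 (SE 0.20). Chac1 missed the threshold without RAG2KO replicate 1 (0.0523) or RAG2KO replicate 2 (0.0582). Immediate early genes were higher in 5 of 21 members and lower in 0 (6 and 0 over the list alone; adjusted p = 0.0108, and 0.961 with an estimated correlation; 0.0978 without RAG2KO replicate 1 and opposite in sign with adjusted p = 0.993 with the Rn45s covariate), with Myc at 0.92 (SE 0.15) and the heat shock gene Hspa1b at 1.13 (SE 0.27), which has a near-identical neighbour, Hspa1a.

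Lists that did not pass here included MHC class I presentation (1 higher, 3 lower of 22, adjusted p = 0.567) and interferon gamma induced genes (2 higher, 1 lower of 21, adjusted p = 0.688). Some lists passed with a library left out. Goblet genes (0 higher, 1 lower of 12, adjusted p = 0.197) did so without C57Bl6 replicate 1 (0.0240) or RAG2KO replicate 2 (0.0131), and identity factors (0 higher, 3 lower of 15, adjusted p = 0.105) without C57Bl6 replicate 3 (0.0408) or RAG2KO replicate 2 (0.0336). Wnt/beta-catenin targets (4 higher, 6 lower of 21, adjusted p = 0.547) passed without C57Bl6 replicate 3 (0.0217), gastric and foregut genes (3 higher, 0 lower of 15, adjusted p = 0.160) without RAG2KO replicate 2 (0.0134), epithelial-mesenchymal transition genes (1 higher, 1 lower of 19, adjusted p = 0.988) without RAG2KO replicate 2 (0.0206) and chemokines (0 higher, 4 lower of 23, adjusted p = 0.484) without RAG2KO replicate 3 (0.0182).

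**Figure D3:**
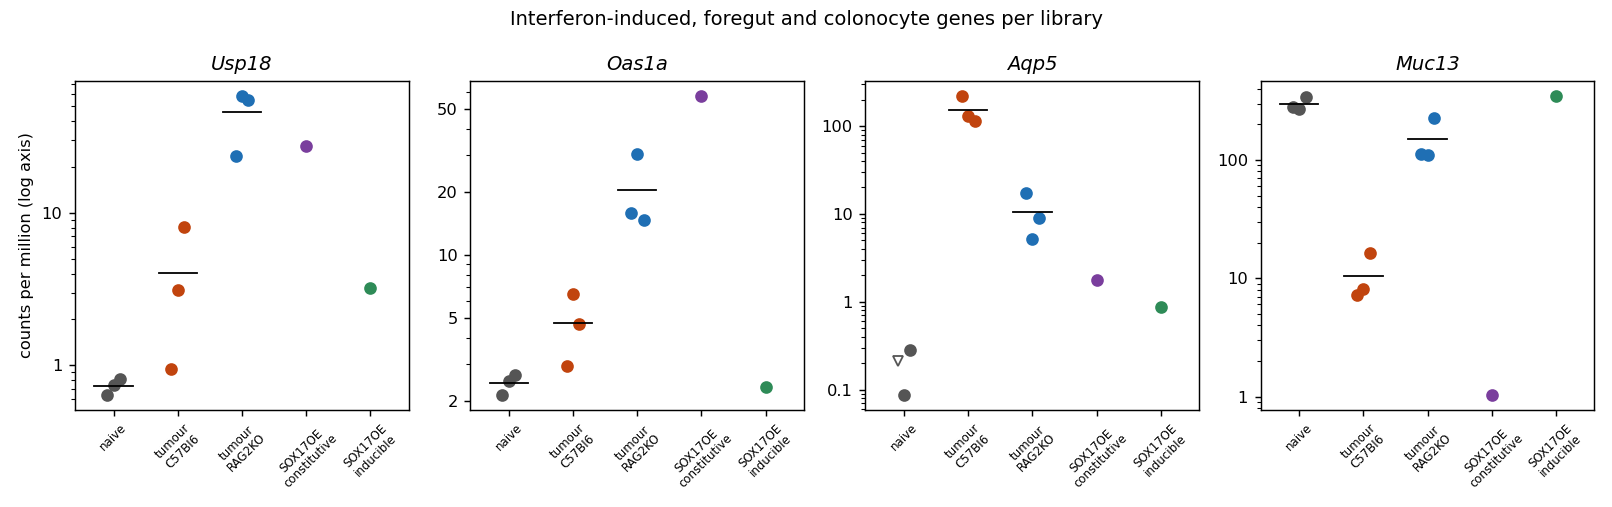
CPM on a log axis of Usp18 and Oas1a (type I interferon induced), Aqp5 (gastric and foregut) and Muc13 (absorptive colonocyte) in the 11 libraries by group. Filled points are libraries, black lines are group means where no library is at 0, and open triangles are libraries at 0 drawn at their floor of 3 counts. Usp18 was 23.5 to 58.3 CPM in the RAG2KO and 0.943 to 8.08 CPM in the C57Bl6 libraries.

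Between recipients 3295 genes differed, 1677 higher and 1618 lower in C57Bl6 tumour-derived organoids, and upper quartile scaling gave 1150 higher and 2017 lower while library totals gave 2263 higher and 1290 lower. The count was 1857 without C57Bl6 replicate 3 and 2018 without RAG2KO replicate 3. With the log2 share of Rn45s as a covariate, chosen after seeing the data, 2 genes were called, and of the 28 called genes that the naming rule gave the text Ms4a8a passed. The adjusted fold changes had a slope of 0.878 on the unadjusted ones (0.715 to 0.970 with a library left out), while the median SE went from 0.175 to 0.367. 7 of the 30 lists passed, 11 without RAG2KO replicate 2. With an estimated correlation camera passed 0 lists, 1 at an unadjusted p under 0.05, and fry passed 2. The median, mean and tested direction differed in sign for fetal genes (-0.05, 0.02, down), interferon gamma signalling (0.02, -0.04, down), NF-kappaB targets (-0.02, -0.09, up), checkpoint ligands (-0.20, -0.33, up), epithelial-mesenchymal transition genes (-0.20, -1.06, up) and endothelial markers (-0.42, 0.11, down).

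The SOX17OE lines were compared with naive organoids to ask which genes differ when SOX17 is expressed without growth in a mouse. Sox17 had 72.7 CPM in the constitutive and 4.78 CPM in the inducible line against 0.102 ± 0.0974 CPM in naive organoids, and their mean rose by 7.63 on the log2 scale (SE 1.04, adjusted p = 0.00454). Ifngr1 fell from 63.9 ± 7.09 CPM to 25.7 and 29.7 CPM (log2 fold change -1.21, SE 0.17, adjusted p = 0.00433). Lgr5 fell from 57.6 ± 12.2 CPM to 1.56 and 6.30 CPM (-4.20, SE 0.45, adjusted p = 0.00151). With the inducible line alone the calls of Sox17 (5.66, adjusted p = 0.0722) and Ifngr1 (-1.10, adjusted p = 0.0600) ended.

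B2m rose by 1.20 (SE 0.17, adjusted p = 0.00395), with 135 CPM in the constitutive and 43.2 CPM in the inducible line, and with the inducible line alone it did not pass (0.37, adjusted p = 0.376). Anxa1 rose by 0.83 (SE 0.20, adjusted p = 0.0258) and Cxcl10 fell by 3.02 (SE 0.64, adjusted p = 0.0188). The call of Anxa1 ended without naive replicate 1 (0.0552), 2 (0.0948) or 3 (0.0630), and that of Cxcl10 without naive replicate 2 (0.0504) or 3 (0.0552). The log2 fold changes of the other fixed genes, which did not pass, were 0.53 for Ifngr2, 0.39 for Irf1, -0.22 for H2-K1, -0.14 for H2-D1, 0.99 for Tap1 and 0.01 for Cd274. They were -0.45 for Ascl2, 0.26 for Ly6a, 0.15 for Trp53 and -0.27 for Apc (adjusted p from 0.112 to 0.9999).

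The largest rises included Tek, the angiopoietin receptor of endothelial cells, at 26.0 CPM in the constitutive and 3.61 CPM in the inducible line (ratio of the lines to naive 287, 95% counting interval 97.6 to 1396, adjusted p = 0.00415). Its ratio was 69.6 with the inducible and 502 with the constitutive line alone, and 174 and 548 without naive replicates 2 and 3. Rhoj, a small GTPase, had 25.5 and 1.98 CPM (ratio 399, interval 110 to 3301, adjusted p = 0.0118), with ratios of 57.3 with the inducible and 736 with the constitutive line alone and 254 without naive replicate 3, and at least 76.8-fold without naive replicate 2. Its call ended without naive replicate 2 (0.0549) or 3 (0.0544). Ifitm6 had 37.6 and 9.91 CPM and was at least 146-fold higher than the floor of 3 counts per library (adjusted p = 0.00593; 60.8-fold with the inducible and 231-fold with the constitutive line alone). The lipoxygenase Alox15 rose by 7.02 (SE 0.33, adjusted p = 1.41e-05), with 46.8 and 16.6 CPM, and Ifitm3 by 7.01 (SE 0.63, adjusted p = 9.18e-04), with 1704 and 71.1 CPM; the Ifitm genes are a family of similar sequences. Among the largest falls 5 genes were at 0 counts in the constitutive line. They were the decarboxylase Ddc (adjusted p = 0.0482), Khdc1c (0.00916), Baiap2l2 (0.00269), Upk1b (0.0347) and Cyp2c55 (0.0217), at 2.51, 28.2, 1.11, 3.03 and 2.97 CPM in the inducible line against 14.6 ± 1.42, 43.1 ± 13.7, 8.12 ± 0.855, 7.83 ± 1.43 and 5.62 ± 0.478 CPM. Without naive replicates 1, 2 and 3 Ddc did not pass (0.0766, 0.107 and 0.115), nor did Upk1b (0.0616, 0.0872 and 0.0961), and Cyp2c55 did not without 2 or 3 (0.0606 and 0.0603).

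Unfolded protein response genes fell in 14 of 20 members and rose in 0 (19 and 0 adjusted over the list alone; adjusted p = 3.43e-13, and adjusted p = 0.480 with an estimated correlation), with Trib3 at -1.96 (SE 0.26) and Chac1 at -1.54 (SE 0.24). Glycolysis and hypoxia genes fell in 7 of 26 members and rose in 1 (11 and 1 over the list alone; adjusted p = 1.14e-06, and 0.480 with an estimated correlation), with the glucose transporter Slc2a1 at -1.99 (SE 0.26) and the carbonic anhydrase Car9 at -4.77 (SE 0.79). Type I interferon induced genes rose in 9 of 26 members and fell in 0 (13 and 0 over the list alone; adjusted p = 1.87e-06, and 0.564 with an estimated correlation; 0.692 without the constitutive line). Mx1, an antiviral GTPase, had 26.9 CPM in the constitutive and 6.59 CPM in the inducible line (4.85, SE 0.51), and Oas1a 57.5 and 2.33 CPM (2.24, SE 0.39; -0.07 with the inducible line alone, adjusted p = 0.963). Proliferation genes fell in 4 of 30 members and rose in 0 (12 and 0 over the list alone; adjusted p = 4.33e-06, and 0.672 with an estimated correlation), with Mki67 at -0.88 (SE 0.20) and Rrm2 at -0.96 (SE 0.23). The call of Mki67 ended without naive replicate 1 (0.0525), 2 (0.0701) or 3 (0.0598), and that of Rrm2 without naive replicate 2 (0.0744) or 3 (0.0623). The share of Rn45s was 6.39% in the constitutive and 3.71% in the inducible line against 2.42 to 4.99% in naive libraries.

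Immediate early genes fell in 6 of 21 members and rose in 0 (12 and 0 adjusted over the list alone; adjusted p = 3.31e-05, and adjusted p = 0.662 with an estimated correlation), with Atf3 at -2.32 (SE 0.49) and Myc at -0.81 (SE 0.18). Epithelial junction and keratin genes fell in 8 of 20 members and rose in 0 (8 and 0 over the list alone; adjusted p = 1.09e-04, and 0.524 with an estimated correlation), with the tight junction gene Cldn3 at -1.14 (SE 0.20) and the E-cadherin gene Cdh1 at -0.95 (SE 0.20). Stem cell markers fell in 4 of 19 members and rose in 0 (6 and 1 over the list alone; adjusted p = 0.00289, and 0.480 with an estimated correlation), with the ephrin receptor Ephb2 at -1.27 (SE 0.26) beside Lgr5. YAP/TAZ targets fell in 3 of 20 members and rose in 1 (6 and 1 over the list alone; adjusted p = 0.0126, and 0.705 with an estimated correlation; 0.0823 without naive replicate 3 and 0.0744 without the inducible line), with Wwc1 at -0.99 (SE 0.23) and Gadd45b at 0.75 (SE 0.16). Without naive replicates 2 and 3 the calls ended of Cdh1 (0.0549 and 0.0503), Ephb2 (0.0524 and 0.0510), Wwc1 (0.0670 and 0.0640) and Gadd45b (0.0720 and 0.0576).

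Absorptive colonocyte genes fell in 4 of 17 members and rose in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.0126, and adjusted p = 0.480 with an estimated correlation; opposite in sign with adjusted p = 0.787 without the constitutive line). Muc13 had 1.04 CPM in the constitutive and 348 CPM in the inducible line (mean log2 fold change -3.96, SE 0.49; 0.23 with the inducible line alone), and the keratin Krt20 91.1 and 10.7 CPM (3.19, SE 0.53). Endothelial markers rose in 2 of 7 members and fell in 0 (3 and 1 over the list alone; adjusted p = 0.0215, and 0.480 with an estimated correlation; 0.0843 without naive replicate 1 and 0.204 without the constitutive line). The members that rose were Tek and the cadherin Cdh5, which had 3.29 and 0.758 CPM and was at least 12.4-fold higher than the floor (4.65-fold with the inducible and 20.2-fold with the constitutive line alone). MHC class I presentation genes (4 higher, 1 lower of 22) and interferon gamma induced genes (4 higher, 2 lower of 21) did not pass with both lines (adjusted p = 0.116 and 0.481), and each passed without the inducible line (0.0222). Wnt/beta-catenin targets (5 higher, 2 lower of 21, adjusted p = 0.116) passed without C57Bl6 replicate 1 (0.0231) or 3 (0.00599), tuft cell genes (1 higher, 0 lower of 6, adjusted p = 0.0548) without naive replicate 3 (0.00997) or the inducible line (0.00345) and NF-kappaB targets (0 higher, 1 lower of 19, adjusted p = 0.1247) without the constitutive line (0.0340).

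Against the mean of both lines 1741 genes changed, 929 higher and 812 lower, and the count was 85 without the constitutive line, 450 without naive replicate 2 and 571 without naive replicate 3. It was 2711 with DESeq2, 3815 with voom and 864 in a fit of only naive and SOX17OE libraries. Of the 36 called genes that the naming rule gave the text, 30 missed the threshold without the constitutive line (adjusted p from 0.0600 to 0.963), and Lgr5, Ifitm6, Alox15, Ifitm3, Mx1 and Slc2a1 passed. 5 missed it without the inducible line (0.0602 to 0.137), Cxcl10, Anxa1, Ddc and Atf3 among them, 5 without naive replicate 1 (0.0525 to 0.0766), 13 without naive replicate 2 (0.0504 to 0.107) and 13 without naive replicate 3 (0.0503 to 0.117). Ddc also missed it without RAG2KO replicate 1 (0.0640), 2 (0.0593) or 3 (0.0574). In each called gene named here except Oas1a and Muc13 both lines lay beyond the 3 naive libraries on the same side. With the log2 share of Rn45s as a covariate, chosen after seeing the data, 267 genes were called, and 17 of the 36 passed. The adjusted fold changes of the 1741 genes had a slope of 1.01 on the unadjusted ones (0.941 to 1.07 with a library left out), and the median SE went from 0.220 to 0.258. 10 of the 30 lists passed, and with an estimated correlation camera passed 0 (1 at an unadjusted p under 0.05) and fry 6. The median, mean and tested direction differed in sign for interferon gamma signalling (0.0041, -0.04, down), chemokines (0.11, -0.13, down), checkpoint ligands (-0.23, 0.13, up), gastric genes (-0.57, 0.25, up), identity factors (0.04, -0.82, down) and fibroblast markers (-0.10, 0.44, up).

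Each line was also compared alone, with its single library assumed to vary like the groups of 3. These comparisons describe 1 culture each and cannot separate the construct from that culture, so single genes are given here without p-values. The p-values above with the inducible line alone are leave-one-out values that rest on the same assumption and have the same limit. The log2 differences from naive of the constitutive line were 9.59 for Sox17, -1.31 for Ifngr1 and -5.20 for Lgr5, and those of the inducible line were 5.66, -1.11 and -3.19, with Alox15 at 6.27. Under that assumption the constitutive line had 1684 called genes, 992 higher and 692 lower (721 without naive replicate 2, 953 without naive replicate 3 and 3176 with voom). The inducible line had 90, 72 higher and 18 lower (13, 12 and 26 without naive replicate 1, 2 and 3, 147 without C57Bl6 replicate 1 and 55 without RAG2KO replicate 1). It was 800 with DESeq2 and 727 with voom. With the Rn45s covariate, chosen after seeing the data, 195 genes were called for the constitutive and 34 for the inducible line.

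The last comparisons ask how far the changes against naive organoids were shared. C57Bl6 and RAG2KO tumour-derived organoids shared 838 genes that rose, Sox17, Igfbp4, Clu and Avil among them, and 343 that fell, and 39 changed in opposite directions. If the calls were independent, 208 and 106 shared genes and 301 opposite ones would arise. SOX17OE and RAG2KO tumour-derived organoids shared 679 genes that rose, B2m among them, and 565 that fell, Lgr5 among them, and 21 were opposite (148, 108 and 253 if independent). SOX17OE and C57Bl6 tumour-derived organoids shared 261 that rose and 132 that fell, and 95 were opposite (88.3, 47.5 and 131 if independent). The share of Rn45s was 6.56 to 8.54% in RAG2KO libraries and 6.39% in the constitutive line against 2.42 to 4.99% in naive libraries. With it as a covariate, chosen after seeing the data, 122 genes were shared between the tumour groups, 69 by SOX17OE and RAG2KO and 101 by SOX17OE and C57Bl6, at the slopes and larger SEs given above. Lgals9 and Vtcn1 rose in all 3, by 3.30 and 4.03 in C57Bl6 and 3.64 and 4.06 in RAG2KO tumour-derived organoids and by 3.01 and 3.16 in SOX17OE. Their list, immune checkpoint and regulatory ligands, did not pass with camera in SOX17OE (3 higher, 2 lower and 14 not passing of 19, adjusted p = 0.635). Arg1, which encodes arginase, had 1 naive count and ratios of 239 (95% counting interval 42.6 to 9499) in C57Bl6, 74.6 (12.9 to 2995) in RAG2KO and 228 (40.2 to 9061) in SOX17OE. Without naive replicate 1, which held the count, it was at least 29.6-fold, 9.30-fold and 28.6-fold above the floor. Without naive replicate 2 the ratios were 145, 45.2 and 138, and without naive replicate 3 they were 153, 47.5 and 145. The ratio in C57Bl6 was 157 without C57Bl6 replicate 3, and that in SOX17OE 87.6 with the inducible and 366 with the constitutive line alone.

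Across genes, which are not independent replicates, the Pearson correlation of the fold changes was 0.683 between both tumour comparisons, 0.591 between SOX17OE and RAG2KO and 0.303 between SOX17OE and C57Bl6. The naive libraries are shared by these comparisons, and 20 simulations of unchanged groups against the same controls gave mean correlations of 0.493, 0.426 and 0.434, with at most 1, 0 and 0 shared genes called by edgeR. The covariances were 0.754, 0.537 and 0.270 against 0.0717, 0.0708 and 0.0721 in the simulations. The correlation of SOX17OE with C57Bl6, 0.303, lay below the range of the 20 simulations, 0.418 to 0.452. The simulated groups held no changed genes, and changes in 1 group alone lower a correlation. The simulated correlations therefore cannot tell whether any of the 3 correlations held an excess. 3 naive libraries cannot be divided into sets of 2 or more for each comparison. Part of the correlations, and of the covariances and shared counts beyond those of the simulations, may therefore come from the shared controls. Without the constitutive line the shared counts with SOX17OE were 72 for RAG2KO and 37 for C57Bl6, and the correlation with C57Bl6 was 0.154. Without naive replicates 1, 2 and 3 the tumour comparisons shared 657, 579 and 770 of 1181 genes. SOX17OE and C57Bl6 then shared 209, 126 and 154 of 393, and SOX17OE and RAG2KO shared 326 of 1244 without naive replicate 2 and 413 without naive replicate 3. Against the mean of both tumour groups Ifngr1 was lower in SOX17OE by a log2 difference of -1.24 (SE 0.16, adjusted p = 0.00171).

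**Figure D4:**
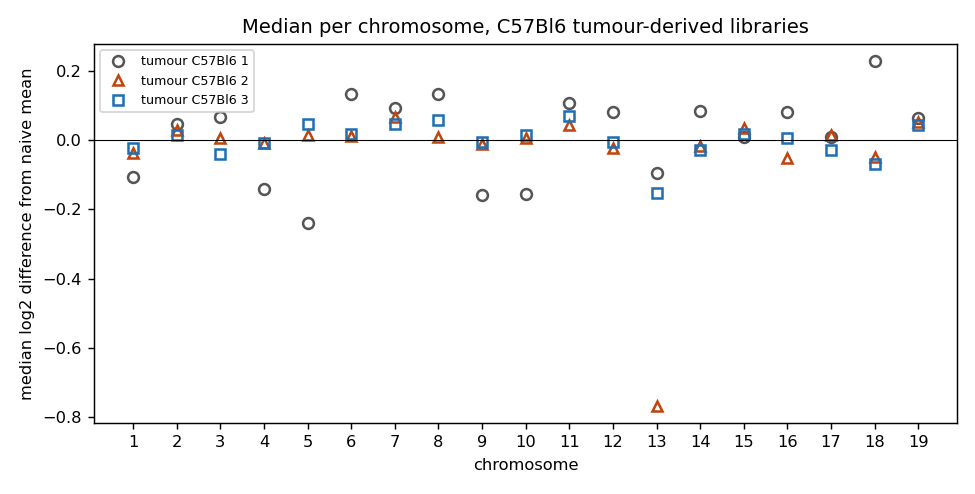
Median log2 difference from the naive mean of the genes of each autosome in the 3 C57Bl6 libraries, with 1 marker shape per library. In replicate 2 chromosome 13 is at -0.77 and each other autosome between -0.05 and 0.07.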

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

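The tests for fewer copies of chromosome 13 and of the slope read from the naive and SOX17OE libraries were set before their results were seen, and the other tests here, the splits of the libraries and the scalings among them, were set up after.

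Of 75 genes named against naive in either tumour comparison, 37 differed between C57Bl6 and RAG2KO tumour-derived organoids in a direct test, and the fold changes of 2, Icam1 and 2210415F13Rik, had opposite signs, neither of which passed in RAG2KO. The difference, C57Bl6 minus RAG2KO in log2, was -0.66 for Ifngr2, -0.79 for Irf1, 1.68 for Lgr5, 3.03 for Igfbp4, 2.97 for Scara3, 4.36 for Fam149a, 4.09 for Dzip1l and 7.86 for Mmp14. It was -2.85 for Gvin1, -4.93 for Ms4a8a, -2.69 for Cyp2c55, -3.34 for Pde4b, -2.84 for Lrrc19, -1.13 for Dkk2, 0.83 for Ccnd1, 1.79 for Clu, 0.74 for Jub, -0.55 for Psme1 and 0.92 for Icam1. For genes of the epithelial lists it was -3.83 for Muc13, -3.86 for 2210415F13Rik, 1.44 for Ptgs1, 3.88 for Aqp5, 1.27 for Onecut2, -0.77 for Hoxb9, -3.82 for Cdx1 and -0.70 for Cd24a. The others were 0.53 for Asns, -1.44 for Tmem150c, 1.07 for Prkaa2, -1.66 for Notum, -2.11 for Oas1a, -3.48 for Usp18, -1.50 for Tnf, 0.96 for Mki67, 0.58 for Bub1b and 1.10 for Trib3. Ifngr1 differed between the SOX17OE lines and the tumour-derived organoids by -1.24.

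The 3 libraries of each group can be split against the 3 of another in 10 ways, so the share of splits is never under 0.1, and in each comparison 1 of the 10, the real one, gave as many genes. The real split gave 2106 genes for C57Bl6 against naive, 4010 for RAG2KO against naive and 3295 between recipients. The highest other split gave 0 with edgeR, and at an unadjusted p under 0.05 it gave 1145, 1526 and 1419 genes.

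Genes of chromosome 13 were lower in C57Bl6 replicate 2, with a median log2 difference from naive of -0.77. Other libraries had smaller shifts of chromosome 13, of -0.26 in RAG2KO replicate 2, -0.15 in C57Bl6 replicate 3 and -0.13 in RAG2KO replicate 3, and C57Bl6 replicate 1 had -0.24 for chromosome 5 and 0.23 for chromosome 18. For C57Bl6 against naive 52 chromosome 13 genes were called lower, 12.4% against 5.58% of the other genes, and 17 without C57Bl6 replicate 2. Scaling of that library is argued against by a median of 0.0148 over the genes of the other autosomes, and a few strongly changed genes by 91.9% of the chromosome 13 genes lying below 0. Fewer copies of the chromosome could explain it, since the weakest of 6 blocks of neighbouring genes had a median of -0.69. Copy number was not measured, and no group of the design gives a biological explanation to test.

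The 3295 genes that differed between recipients go with the share of Rn45s, which was higher in each RAG2KO library. The choice among the scalings tried is argued against as the source of most calls, since at least 84.0% of the genes were called again under each. The balance of higher and lower genes did move with the scaling. The median log2 fold change shifted by -0.100 under upper quartile scaling and by 0.094 under library totals. An error common to all the scalings was not tested. In the naive and SOX17OE libraries the change per unit of Rn45s share had a slope of 0.132 on the difference between recipients, 0.106 to 0.163 with a library left out, which argues against a share effect that works alike in all libraries. With the share as a covariate the slope of adjusted on unadjusted fold changes was 0.878 (0.715 without C57Bl6 replicate 1). Nearly all calls ended, while the median SE went from 0.175 to 0.367 and the median absolute log2 fold change from 0.794 to 0.668. Which of these changes ended the calls was not tested. The share and the recipient cannot be told apart in these 6 libraries, and a difference between recipients may also be the cause but stays untested.

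Type I interferon induced genes were higher in RAG2KO than in C57Bl6 tumour-derived organoids in 14 of 26 members and lower in 0. The list passed with camera at the preset correlation (adjusted p = 1.41e-07) but not at an estimated one (0.862), nor with fry (0.0735). Host immune cells as the main source are argued against by 35 myeloid or lymphoid markers under 1 CPM in naive organoids. Their largest rise was 0.593 CPM, for Cd79b, next to 41.4 CPM for Usp18. Lyz2, Tyrobp, Fcer1g, C1qa and Ptprc stayed at or under 0.175 CPM in RAG2KO libraries, while Itgam and Csf1r reached 1.81 and 1.28 CPM. Csf1r averaged 0.710 CPM in RAG2KO, 0.261 CPM in C57Bl6 and 0.0476 CPM in naive organoids. Of 8 myeloid markers tested, 2 were called higher and 1 lower in RAG2KO than in naive organoids. In C57Bl6 against RAG2KO 0 were called higher and 1 lower. Host cells other than immune cells were not tested as a source. T and B cell markers weigh little in these recipients. Among markers above 1 CPM in naive organoids, Cd14, S100a8, Cd68 and S100a9 were higher in RAG2KO than in C57Bl6. Cd14 differed by 15.1 and S100a8 by 9.58 CPM, and Mrc1 by -0.773 CPM. Naive organoids held 33.7 CPM of Cd14 and 20.04 CPM of S100a8, so these markers cannot tell host cells from organoid expression. With the Rn45s covariate the median of the list was -1.24 against -1.56 without it, and from -0.32 without naive replicate 1 to -2.21 without RAG2KO replicate 1, so an effect of the share may account for part and stays open. A response to the recipient's immune status is the biological explanation the design gives, and it was not tested apart from the share. The list was also high in the 1 library of the constitutive line, which did not grow in a mouse. Its median log2 difference from naive was 2.75 there, with Rn45s at 6.39%, against 0.73, 2.51 and 2.06 in the RAG2KO libraries. In the inducible line it was -0.18, with Rn45s at 3.71%. A rise of this list was therefore seen in 1 library without a recipient, in which construct, culture and Rn45s share cannot be told apart. What raised the list in the RAG2KO libraries cannot be read from it.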

How the results depend on the processing

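The Rn45s covariate and the fit without chromosome 13 genes were chosen after seeing the data. Of the values of single named genes under the alternatives, 8494 kept their side of the threshold, 783 no longer passed, 23 newly passed and 3 reversed. Direction was compared only where a gene passed in the main fit or under the alternative. The cause of the changes below was not tested, except that fits without a library, or of fewer libraries, have fewer samples. A gene with few counts and each single SOX17OE library limit what could be called.

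The counts of genes stayed within 1.5 times under the other scalings, both filters and the non-robust fit. Without a filter 7 lists passed for C57Bl6 and 6 for RAG2KO against naive. DESeq2 called 2711 genes for SOX17OE and 800 for the inducible line, and shared 657 with C57Bl6 and 1895 with RAG2KO. Voom called 4067 for C57Bl6, 3815 for SOX17OE, 3176 for the constitutive and 727 for the inducible line, with overlaps of 2020 between tumour groups, 1017 of SOX17OE with C57Bl6 and 2616 with RAG2KO. The fit of naive and SOX17OE libraries called 864. The Rn45s covariate left 148 genes for RAG2KO, 2 between recipients, 267 for SOX17OE, 195 for the constitutive and 34 for the inducible line, and overlaps of 122, 101 and 69; Cadps reversed between recipients to -0.26 and the immediate early list reversed at adjusted p = 0.993. With an estimated correlation 1 list passed for C57Bl6, 1 for RAG2KO, 0 between recipients and 0 for SOX17OE by camera (4, 3, 1 and 1 at an unadjusted p under 0.05), and by fry 8 for C57Bl6, 2 between recipients and 6 for SOX17OE. For SOX17OE, leaving out a library gave -0.068 (reversed, without the constitutive line) to 4.55 for Oas1a, -8.15 to 0.23 (reversed, same line) for Muc13, and adjusted p = 5.16e-04 to 0.787 (reversed, same line) for the absorptive list. A replicate block gave 1737, 3453 and 2688 genes in the tumour comparisons; the numbers do not pair libraries, as 0 of 9 correlate best with their own number in both other groups.

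With a library left out, calls ranged from 1030 to 2328 for C57Bl6 (lowest without naive replicate 2), 2041 to 4184 for RAG2KO (naive replicate 2), 1857 to 3311 between recipients (C57Bl6 replicate 3), 85 to 1931 for SOX17OE (constitutive), 721 to 1900 for the constitutive (naive replicate 2) and 12 to 147 for the inducible line (naive replicate 2). Overlaps ranged from 579 to 1182 between tumour groups (naive replicate 2), 37 to 482 for SOX17OE with C57Bl6 and 72 to 1373 with RAG2KO (constitutive). Lists ranged from 7 to 14 for C57Bl6 (C57Bl6 replicate 1), 9 to 15 for RAG2KO, 5 to 11 between recipients and 9 to 12 for SOX17OE. Correlations ranged from 0.648 to 0.701 between tumour groups, and from 0.154 to 0.358 for SOX17OE with C57Bl6 and 0.461 to 0.611 with RAG2KO (both lowest without the constitutive line).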

Other observations

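9 lists passed in no comparison. The counts that follow are higher and lower called members for C57Bl6 against naive, RAG2KO against naive, C57Bl6 against RAG2KO and SOX17OE against naive, in that order. Endoderm and SOXF factors, 12 tested, had 2 and 2, 3 and 3, 0 and 1, and 2 and 3 (adjusted p = 0.742, 0.943, 0.898 and 0.548). Among them Hnf4a fell by 1.49 in C57Bl6 tumour-derived organoids, and Gata6 fell by 2.39 in SOX17OE. MHC class II genes, 5 tested, had 2 and 0, 0 and 1, 0 and 0, and 0 and 0 (0.214, 0.684, 0.567 and 0.865), with Cd74 higher by 2.56 and H2-Ab1 by 3.35 in C57Bl6 tumour-derived organoids. Interferon gamma signalling genes, 15 tested, had 2 and 1, 4 and 1, 2 and 3, and 1 and 1 (0.382, 0.303, 0.904 and 0.865).

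Goblet genes, 12 tested, had 0 and 2, 1 and 1, 0 and 1, and 1 and 0 (adjusted p = 0.214, 0.943, 0.197 and 0.348), and Atoh1 fell by 6.59 in C57Bl6 and by 2.47 in RAG2KO tumour-derived organoids. Enteroendocrine genes, 5 tested, had 0 and 1, 1 and 0, 0 and 0, and 0 and 0 (0.925, 0.715, 0.638 and 0.658). Cholesterol synthesis genes, 23 tested, had 1 and 1, 8 and 1, 3 and 9, and 0 and 1 (0.932, 0.118, 0.160 and 0.557), and with fry adjusted p = 6.02e-04 for RAG2KO against naive and 0.00781 between recipients; for SOX17OE the list passed without the constitutive line (0.00286). p53 targets, 21 tested, had 1 and 0, 1 and 4, 2 and 1, and 1 and 1 (0.932, 0.930, 0.904 and 0.658). Fibroblast markers, 6 tested, had 2 and 0, 2 and 0, 0 and 0, and 1 and 0 (0.147, 0.118, 0.904 and 0.633), with Acta2 higher by 2.88 in C57Bl6 and 2.89 in RAG2KO tumour-derived organoids. Myeloid markers, 8 tested, had 0 and 1, 2 and 1, 0 and 1, and 0 and 1 (0.395, 0.943, 0.532 and 0.161).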
